A study of Mus musculus with 8 samples.

How the data were processed

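Gene expression was measured on Affymetrix mouse gene arrays in 4 populations of dendritic cell progenitors sorted from mouse bone marrow, with 2 arrays per population and 8 arrays in total. CDP, the field's name for the common dendritic cell progenitor, and pre-CD8, a progenitor named by the labels without further definition, were each divided by fluorescence of a green reporter placed in the Id2 gene. Per the labels' protocols, marrow cells were freed of red blood cells, sorted on a flow cytometer, and total RNA was extracted on columns and labelled with a kit for very small RNA inputs. The sort gates are not given in the labels. Sample titles, sources and descriptions name the Id2 reporter throughout, but the genotype field names it for 2 samples, both Id2-GFP- CDP, and names a different reporter, Zbtb46-GFP, for the other 6. Groups were taken from the titles.

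The deposited table holds intensity values for 28853 probe sets on a linear scale. Per the submitters' processing notes, the authors used RMA in Affymetrix Expression Console, and no version of either is stated. RMA corrects background, normalises across arrays and summarises the probes of a set, so that low values are compressed towards a floor and differences of dim genes are understated. No detection call or background measure was used here. The deposited intensity values were converted to log2 and not normalised again. The design had assumed log2 values, to be taken first if the table was linear.

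Gene names came from the array's annotation. It gave 1 symbol to 21789 probe sets, several symbols to 1621 and no entry to 5443. Entrez identifiers placed 21698 of the 1-symbol probe sets in a RefSeq gene table, which changed 0 symbols. Probe sets with several symbols or none were left out of gene tests. Where a gene had more than 1 probe set, as 999 genes did, the one with the highest mean over the 8 arrays was used, which left 19938 genes. Genomic positions were not used here. Probes of near-identical paralogs can respond to each other's transcripts, so values of such families are less certain.

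The statistical test was limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups, all 8 arrays in a single fit, a variance prior with an intensity trend and no filter on dim genes. The fit had 4 residual degrees of freedom, a prior of 4.19 and a total of 8.19. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was the threshold. All 6 pairs of groups were compared, and an interaction contrast tested whether the reporter difference in pre-CD8 differed from that in CDP. Python 3.11.15 was used for data preparation and figures.

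Differences are log2 values with the standard error of the limma fit, each between groups of 2 arrays, and their signs follow the order of the groups as named. The number of arrays limits the precision. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these arrays, which may be technical. In data simulated with spread that was independent between arrays, 26% of changes of log2 1 were recovered in the reporter comparison of CDP, 78% of changes of log2 2, 92% of log2 3 and 100% of log2 4, over 19938 genes with 50 changed at each size.

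Tests, groups, gene lists and the rule for named genes were set before the data were examined. The rule named Id2 first. It then took up to 10 rising and 10 falling genes per pair of groups with the largest differences among those past the threshold, both arrays of one group being above both of the other. Up to 4 members of each list with the smallest p, a fixed set of regulators and receptors, and 10 genes of the interaction completed it; where nothing passed, 5 genes with the smallest p were named as not passing. Predicted genes, receptor families of smell, small RNAs and antigen receptor segments were left out of the part based on size.

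The 26 gene lists covered markers of cDC1, cDC2, pDC, shared conventional dendritic cell, early progenitor, monocyte and macrophage, neutrophil and granule, B lineage, T, NK and ILC, erythroid and megakaryocyte, and basophil, mast cell and eosinophil identity. They also covered the MHC class I and class II pathways, S phase, G2 and M phase, ribosome biogenesis, interferon response, immediate early and stress genes, cholesterol synthesis, oxidative phosphorylation, chemokine receptors and migration, toll-like receptors and adaptors, helix-loop-helix genes (E proteins, Id proteins, Lyl1, Tal1 and Mxd4), dendritic cell transcription factors, surface genes of progenitor gates, and sex-linked genes. Id2 was left out of every list. Shifts of lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison by Benjamini-Hochberg, and repeated with a correlation estimated from the residuals and with fry, which tests whether a list moves on balance one way without comparing it with other genes. With an estimated correlation camera tests on the residual degrees of freedom of the fit, 4 here, so that repeat had little power. A list that did not pass in it is not thereby shown to be unshifted. Members past the threshold were counted over all genes and again adjusted over the list alone.

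The arrays fell into a brighter and a dimmer set, each with 1 array of every group. No scan date or other batch label was used here. A fit with the set as an additive term and differences within each set were therefore added, chosen after seeing the data. Other settings, fixed before the values were seen, were quantile normalization, median centring, a filter keeping the upper 60% of genes by mean, the mean of all probe sets of a gene, testing all probe sets, variance priors without trend or with robust estimation, array weights, fitting only the arrays compared, the replicate number as a block, an added threshold of log2 1, and leaving out each array in turn.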

Results

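Messenger RNA was profiled in dendritic cell progenitors of mouse bone marrow, sorted by stage and by the green fluorescence of an Id2 reporter. The 4 populations compared, with 2 arrays each, were CDP and pre-CD8, each divided into Id2-GFP- and Id2-GFP+ cells. The submitters' stated purpose was to obtain expression signatures of these progenitors and their order along development. Median log2 intensity lay between 6.12 and 6.27 on all 8 arrays, and replicate arrays correlated across genes with r from 0.984 to 0.989. Mean intensity split the arrays into a brighter set (461 to 478) and a dimmer set (402 to 414) with 1 array of each group in each set. The interquartile range of log2 intensity was 3.65 to 3.73 in the brighter set and 3.15 to 3.41 in the dimmer set. Replicate 1 of Id2-GFP+ CDP and of Id2-GFP+ pre-CD8, both dimmer, correlated with r of 0.992, above the 0.984 of the Id2-GFP+ CDP replicates. Counts with the set as a block, and differences within both sets for some results, both chosen after seeing the data, are given beside most results.

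Id2, a helix-loop-helix protein that binds and inhibits E proteins, was measured first because the sort was made on its reporter. Its log2 intensity was 5.72 ± 0.82 (SD, n = 2) in Id2-GFP- CDP, 9.52 ± 0.36 in Id2-GFP+ CDP, 6.54 ± 0.91 in Id2-GFP- pre-CD8 and 10.84 ± 0.21 in Id2-GFP+ pre-CD8. The difference between reporter classes was 3.79 ± 0.48 (log2 ± SE) in CDP, with an adjusted p of 0.017, and 4.30 ± 0.48 in pre-CD8, with an adjusted p of 0.0022. Within the brighter and the dimmer set the CDP difference was 4.12 and 3.47, and the pre-CD8 difference was 5.09 and 3.51. The CDP call was lost without Id2-GFP- CDP replicate 1 or either Id2-GFP+ CDP array, with an adjusted p of at most 0.112. The Id2 transcript was higher on all 4 arrays titled Id2-GFP+ than on all 4 titled Id2-GFP-, and so was Zbtb46 (6.96 to 8.04 against 5.48 to 6.13). Neither transcript decides which reporter was sorted. The genotype field names the Id2 reporter for both Id2-GFP- CDP samples and the Zbtb46 reporter for the other 6. Every comparison with Id2-GFP- CDP, the CDP reporter comparison included, also sets samples of different genotype fields against each other.

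**Figure D1:**
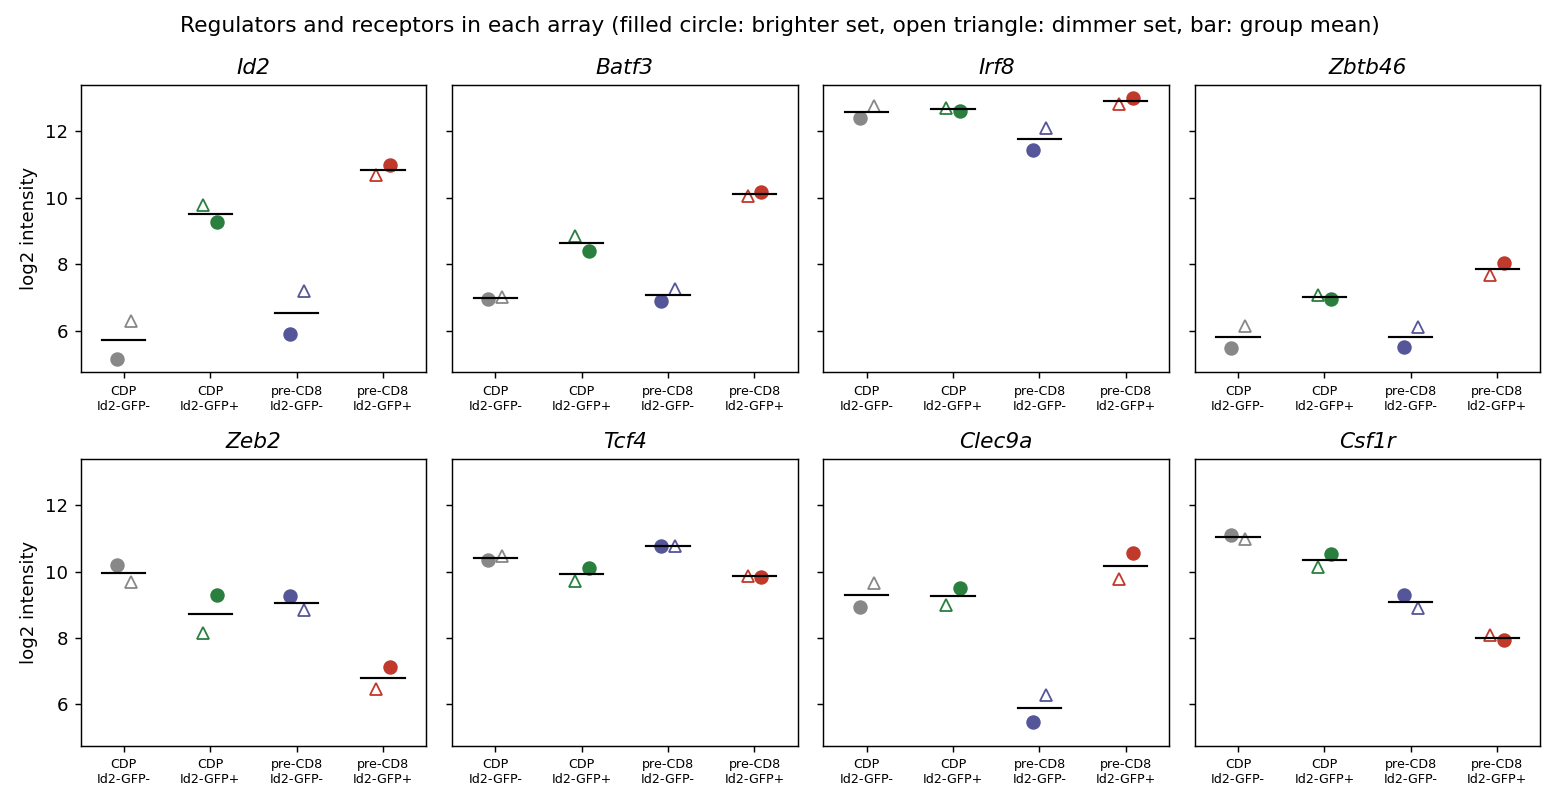
Log2 intensity (vertical axis) of 8 regulators and receptors on each of the 8 arrays, by population (horizontal axis), with filled circles for the brighter array set, open triangles for the dimmer set and bars for group means of 2 arrays. Id2 and Batf3 lie highest in Id2-GFP+ pre-CD8 cells, and Clec9a lies near 5.88 in Id2-GFP- pre-CD8 cells against 9.28 in Id2-GFP- CDP cells.

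The reporter was first compared at the CDP stage. From Id2-GFP- CDP to Id2-GFP+ CDP H2-Aa, a chain of MHC class II, rose by 4.97 ± 0.28 and the invariant chain Cd74 by 4.40 ± 0.32. The granule and secreted defence genes Ltf (lactoferrin), Lcn2 (lipocalin 2), S100a8 (a calprotectin subunit) and Camp (cathelicidin) rose by 4.84 ± 0.40, 4.75 ± 0.39, 4.50 ± 0.30 and 4.29 ± 0.28. Chil3, a chitinase-like protein of myeloid cells, rose by 4.96 ± 0.38, Plbd1, a phospholipase-like protein, by 4.62 ± 0.31 and Ifi205, of the interferon-inducible Ifi200 family, by 4.37 ± 0.37. Fcnb, a ficolin made by myeloid cells, rose by 4.51 ± 0.54. By limma 119 genes rose and 0 fell at an adjusted p under 0.05, 1098 had an unadjusted p under 0.05, and quantile normalization gave 189 and 7. With the array set as a block 735 rose and 831 fell, and all 119 kept their call. Without Id2-GFP- CDP replicate 1, Id2-GFP- CDP replicate 2 or Id2-GFP+ CDP replicate 2 the count was 35, 59 or 42. Fcnb lost its call without Id2-GFP- CDP replicate 2 or Id2-GFP+ CDP replicate 2, with an adjusted p of at most 0.0546.

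Among the lists, 9 of 15 neutrophil and granule genes rose in Id2-GFP+ CDP (11 adjusted over the list alone), with a list median of 3.41, and of 3.12 and 3.26 within the brighter and dimmer sets. Of 9 MHC class II pathway genes 5 rose (6 adjusted over the list alone), with H2-Ab1 at 2.93, and the median of the list was 1.98. 5 of 22 markers of cDC1, the cross-presenting class of dendritic cells, rose (9 adjusted over the list alone), among them the adhesion receptor Cd226 at 3.37 ± 0.24, Tlr3 at 2.36 and Batf3, a transcription factor needed for cDC1, at 1.65 ± 0.23. Camera gave adjusted p-values of 1.94e-26, 1.34e-21 and 9.32e-14 for these lists, against adjusted p = 0.127, 0.113 and 0.113 with an estimated correlation. The median of the cDC1 list was 0.42, and that of 17 cDC2 markers was 0.49. Of the cDC2 markers 1 rose (4 adjusted over the list alone, and 8 with the set as a block). Camera's adjusted p for cDC2 was 9.29e-07, or adjusted p = 0.141 with an estimated correlation. 3 of 16 monocyte and macrophage markers rose (7 rose and 1 fell adjusted over the list alone), with the lysozyme gene Lyz2 at 2.83, and camera's adjusted p was 3.01e-05, or adjusted p = 0.169 with an estimated correlation. 1 of 19 T, NK and ILC markers, the NK receptor Ncr1 at 1.83, rose (8 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation), as did 1 of 17 chemokine and migration genes (5 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation). Batf3 lost its call without any 1 of the 4 CDP arrays and Tlr3 without 5 of the 8, with adjusted p-values of at most 0.230 and 0.239. With the set as a block 9 cDC1 markers, 7 MHC class II genes, 9 T, NK and ILC markers and 5 chemokine and migration genes rose, 11 neutrophil and granule genes rose and 2 fell, and 7 monocyte markers rose and 2 fell.

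Several regulators did not pass between reporter classes in CDP. Irf8, a transcription factor of dendritic cells and monocytes, differed by 0.08 ± 0.22, the dead-cell receptor Clec9a by -0.02 ± 0.40, Zeb2, a zinc-finger repressor, by -1.22 ± 0.41 and Zbtb46, a factor of conventional dendritic cells, by 1.21 ± 0.29. Kit, Id1 and Id3 differed by 0.10, 0.57 and 0.01. Zeb2 and Zbtb46 passed with the set as a block (adjusted p of 0.00172 and 0.00806) and the other 5 did not. Of 32 dendritic cell transcription factors 2 rose in the fit without it (3 adjusted over the list alone, adjusted p = 0.219 with an estimated correlation) against 9 rising and 4 falling with it. Within lists, 25 ribosome biogenesis genes had a median of -0.58 with no member passing by limma over all genes (17 fell with the set as a block), and camera's adjusted p was 7.64e-10 (adjusted p = 0.416 with an estimated correlation). Of 12 basophil, mast cell and eosinophil markers 1, the histidine decarboxylase gene Hdc, rose by 1.92 (1 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation), a call lost without either Id2-GFP- CDP array or Id2-GFP+ CDP replicate 2, with an adjusted p of at most 0.154. The 34 G2 and M phase genes had a median of 0.37 with no member passing by limma over all genes or over the list alone (13 rose with the set as a block, adjusted p = 0.416 with an estimated correlation). The median of 13 erythroid and megakaryocyte markers was 0.11 and that of 12 MHC class I pathway genes was -0.07, with camera adjusted p-values of 0.182 and 0.905. 16 cholesterol synthesis genes had a median of -0.04 and 4 sex-linked genes a median of -0.04, with adjusted p-values of 0.98 and 0.658.

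The same comparison in pre-CD8 cells gave differences in both directions. Highest in Id2-GFP+ pre-CD8 over Id2-GFP- pre-CD8 were Ifi205 at 5.44 ± 0.37, Cd226 at 5.02 ± 0.24, the serpin Serpinb10 at 4.89 ± 0.42, Plbd1 at 4.81 ± 0.31 and Slamf7, a receptor of immune cells, at 4.66 ± 0.43. Naaa, a lipid amidase, rose by 4.45 ± 0.30, Tlr3, a sensor of double-stranded RNA, by 4.32 ± 0.35, Cd22 by 4.29 ± 0.57 and Clec9a by 4.29 ± 0.40. Among falling genes Dntt, which adds nucleotides at antigen receptor joints, fell by 4.24 ± 0.47, the adaptor Blnk by 3.93 ± 0.34, the recombinase genes Rag1 and Rag2 by 3.91 ± 0.32 and 3.09 ± 0.14, and Il7r, the interleukin 7 receptor, by 3.91 ± 0.26. Cmah, Myl10, Gbp7, Tlr7 and Cd69 fell by 3.69, 3.58, 3.49, 3.38 and 3.37, and Il12a, a cytokine subunit gene, lay at -3.39. By limma 711 genes rose and 538 fell, and with the array set as a block 2197 rose and 2625 fell, including all 1249 of these. Without Id2-GFP- pre-CD8 replicate 1 or 2 the total was 627 or 621, and without Id2-GFP+ pre-CD8 replicate 1 or 2 it was 818 or 466, while the 20 genes named by size kept their calls without each of the 8 arrays in turn.

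Of 22 cDC1 markers 14 rose in Id2-GFP+ pre-CD8 (17 adjusted over the list alone), with a median of 1.25, and of 1.49 and 1.06 within the brighter and dimmer sets. Camera's adjusted p was 7.36e-21, or adjusted p = 0.187 with an estimated correlation. Batf3 rose by 3.04 ± 0.23. 7 of 9 MHC class II genes rose, including H2-Eb1 at 3.98, H2-Aa at 3.94, Cd74 at 3.80 and H2-Ab1 at 3.34, and H2-Ob, which opposes peptide loading in B cells, fell by 1.21 (8 rose and 1 fell adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). Beside them, 10 of 15 neutrophil and granule genes rose and 1, Mpo, fell by 1.96 (11 and 2 adjusted over the list alone). That list had a median of 2.48, and of 2.68 and 2.21 within the sets, with S100a8 at 2.92, Camp at 2.81 and S100a9 at 2.48 (camera adjusted p of 6.56e-10, and adjusted p = 0.279 with an estimated correlation). 6 of 16 monocyte and macrophage markers rose and 1 fell (9 and 2 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation), with the chemokine receptor Ccr2 at 4.11 ± 0.20 and Ms4a6c at 2.02. With the set as a block 17 cDC1 markers rose, and 8 MHC class II genes, 12 neutrophil and granule genes and 10 monocyte markers rose while 1, 2 and 2 fell.

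Mitotic genes were higher in Id2-GFP+ than in Id2-GFP- pre-CD8 cells. Of 34 G2 and M phase genes 28 rose (33 adjusted over the list alone), with a list median of 1.49. Among them were the kinetochore gene Nuf2 at 1.84, the ubiquitin-conjugating enzyme gene Ube2c at 1.82, the survivin gene Birc5 at 1.81 and the spindle gene Nusap1 at 1.80. Camera's adjusted p was 2.53e-33, against adjusted p = 0.187 with an estimated correlation. 2 of 29 S phase genes rose (3 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.745 with an estimated correlation). 2 of 16 cholesterol synthesis genes rose (3 adjusted over the list alone), with the farnesyl pyrophosphate synthase gene Fdps at 1.38 and a median of 0.45 (adjusted p = 0.187 with an estimated correlation). The set as a block gave 34 rising G2 and M phase genes, 10 rising and 3 falling S phase genes and 9 rising and 1 falling cholesterol synthesis genes. Id2-GFP- pre-CD8 cells also lay below both CDP groups in Nuf2, at -1.41 against Id2-GFP- CDP and -1.79 against Id2-GFP+ CDP. Birc5 lay at -1.35 and -1.81 in the same comparisons. Between Id2-GFP+ pre-CD8 and Id2-GFP+ CDP 0 genes passed by limma.

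Early progenitor genes were lower in Id2-GFP+ than in Id2-GFP- pre-CD8 cells, 12 of 24 falling (16 adjusted over the list alone) with a median of -1.41. Cd93, the endothelial and progenitor gene Egfl7, the homeobox gene Hoxa9 and Mycn fell by 2.65, 2.59, 2.36 and 2.04. 8 of 20 pDC markers fell and 1, Tlr9, rose by 2.15 (9 and 2 adjusted over the list alone), with a median of -0.64. 7 of 21 interferon response genes fell and 1 rose (10 and 2 adjusted over the list alone), with Rtp4 at -3.08, Oasl2 at -2.54 and a median of -0.81. Camera's adjusted p-values for the 3 lists were 5.63e-12, 0.00116 and 1.8e-04, against adjusted p = 0.279, 0.397 and 0.459 with an estimated correlation. 5 of 16 B lineage markers fell and 3 rose (6 and 3 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation), Bank1 falling by 1.95 and the Fc receptor-like gene Fcrla rising by 2.60. 4 of 19 T, NK and ILC markers rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.397 with an estimated correlation). The set as a block gave 3 rising and 18 falling early progenitor genes, 2 and 11 pDC markers, 3 and 13 interferon response genes, 3 and 7 B lineage markers and 8 and 3 T, NK and ILC markers. Hoxa9 averaged log2 9.46 in Id2-GFP- pre-CD8 against 7.10 to 7.95 in the other groups. Mycn was higher by 3.24 in Id2-GFP- pre-CD8 than in either CDP group. Cd93, in contrast, lay 2.64 lower in Id2-GFP+ pre-CD8 than in Id2-GFP- CDP.

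Transcription factors moved both ways between the pre-CD8 classes. Of 32 dendritic cell transcription factors 8 rose and 3 fell (9 and 5 adjusted over the list alone), with a camera adjusted p of 0.0714, and 11 rose and 8 fell with the set as a block. Klf4 rose by 3.26, Bcl6 by 2.66, Zbtb46 by 2.05 ± 0.29, Mycl by 2.01 and Irf8 by 1.14 ± 0.22, and Zeb2 fell by 2.26 ± 0.41. Of 8 helix-loop-helix genes (Tcf3, Tcf4, Tcf12, Id1, Id3, Lyl1, Tal1 and Mxd4) 3 fell, with the E protein gene Tcf4 at -0.91 ± 0.19, Mxd4 at -1.45 and Lyl1 at -0.90 (3 adjusted over the list alone, adjusted p = 0.373 with an estimated correlation). With the set as a block 4 fell. Flt3 and Csf1r, growth factor receptors of dendritic cell and monocyte progenitors, fell by 1.11 ± 0.26 and 1.09 ± 0.23. The pDC genes Siglech and Ly6d did not pass at -1.66 ± 0.60 and -1.41 ± 0.61, nor did Nfil3, Kit and Xcr1 at 0.11, 0.27 and 0.24. Irf8 lost its call without Id2-GFP- pre-CD8 replicate 1 or either Id2-GFP+ pre-CD8 array (adjusted p up to 0.146) and Zeb2 without replicate 1 of either pre-CD8 group (up to 0.0827). Mxd4 lost it without 2 arrays, and Tcf4, Lyl1, Flt3 and Csf1r each without 6 of the 8, with adjusted p-values of at most 0.241.

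Further lists were counted in the pre-CD8 comparison. 5 of 16 toll-like receptor and adaptor genes rose and 1 fell (9 and 1 adjusted over the list alone), with Tlr1 at 3.05 and Tlr7 at -3.38 (adjusted p = 0.28 with an estimated correlation). 6 of 17 chemokine and migration genes rose and 1 fell (7 and 2 adjusted over the list alone), with Itgb7 at 2.84 and Gpr183 at 2.31 (adjusted p = 0.187 with an estimated correlation). 5 of 17 shared conventional dendritic cell markers rose and 3 fell (7 and 3 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation), and 4 of 17 cDC2 markers rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.397 with an estimated correlation). Of 20 immediate early and stress genes 3 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.397 with an estimated correlation), and their median of 0.41 was 0.71 and 0.14 within the sets. 4 of 14 surface genes of progenitor gates rose and 4 fell (5 and 6 adjusted over the list alone, camera adjusted p of 0.958). 1 of 29 oxidative phosphorylation genes rose over all genes, with a list median of 0.01 (camera adjusted p of 0.467). 12 basophil, mast cell and eosinophil markers had a median of 0.09 with 1 rising only when adjusted over the list alone (camera adjusted p of 0.228), and 13 erythroid and megakaryocyte markers a median of -0.05 (adjusted p of 0.427). The set as a block gave 10 rising and 1 falling toll-like receptor and adaptor genes, 8 and 3 chemokine and migration genes, 7 and 4 shared conventional dendritic cell markers, and 7 and 3 cDC2 markers. It gave 8 and 1 immediate early and stress genes, 7 and 7 surface genes of progenitor gates, 3 and 2 oxidative phosphorylation genes and 4 rising basophil markers.

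**Figure D2:**
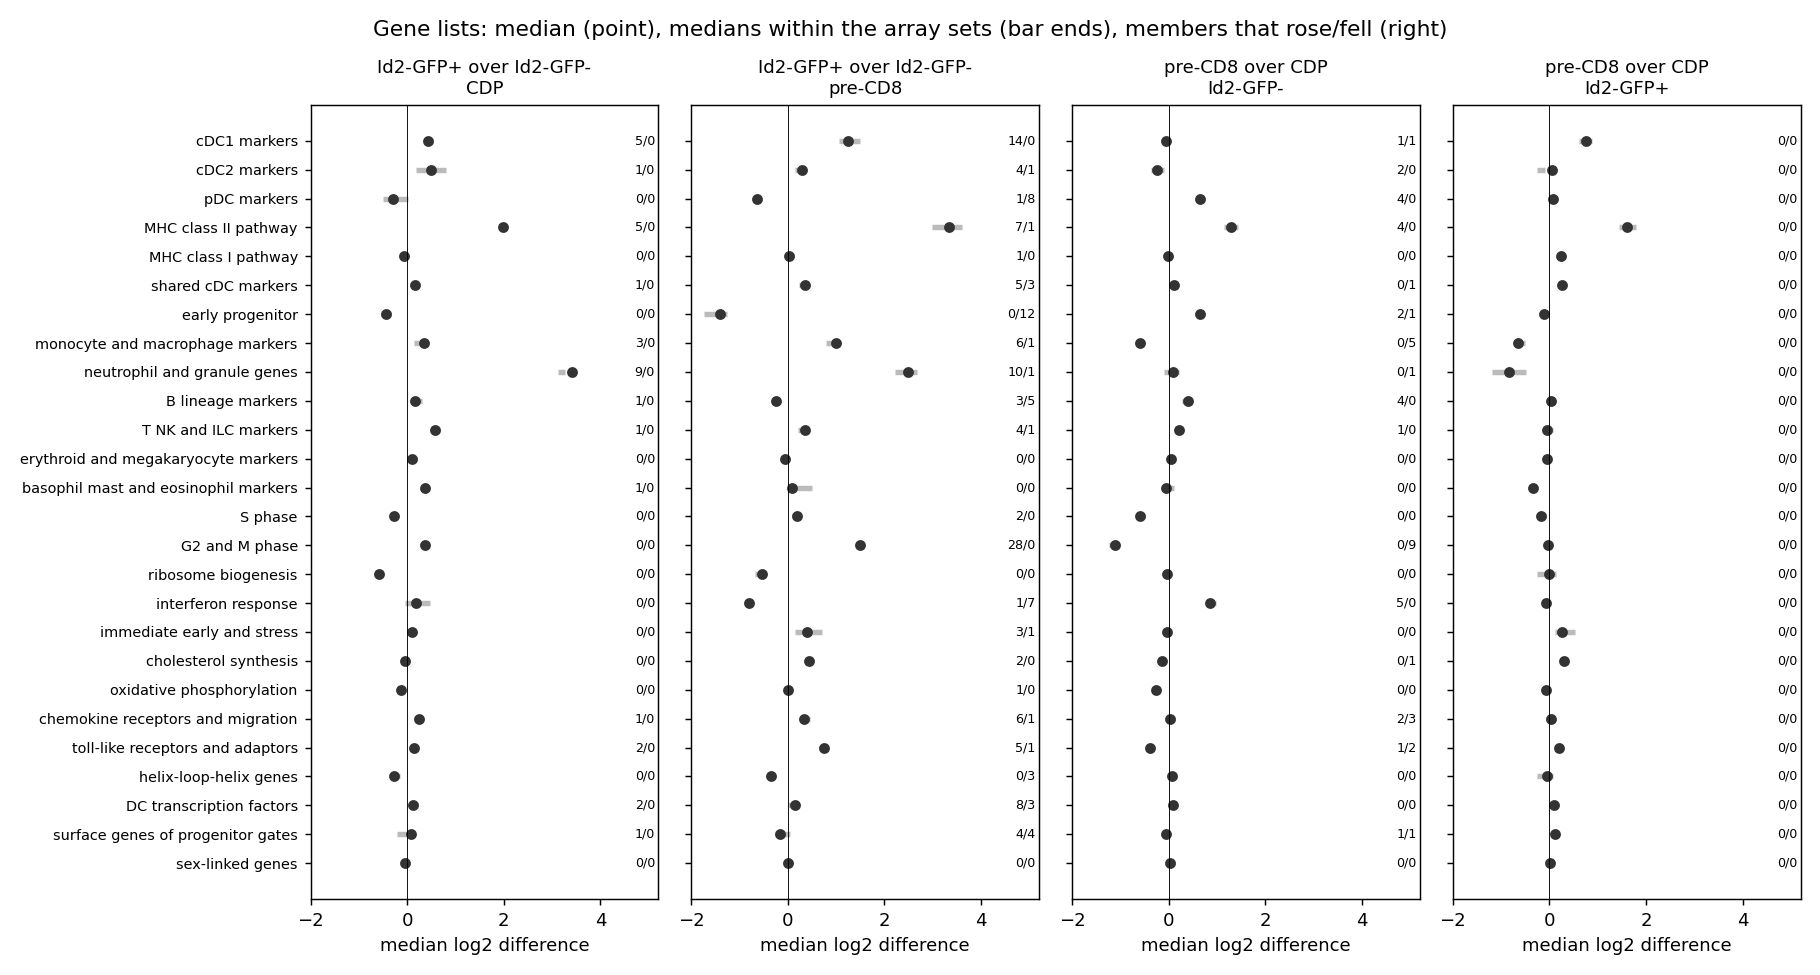
Median log2 difference (horizontal axis) of the 26 gene lists (vertical axis) in 4 comparisons, as points, with grey bars joining the medians within the brighter and dimmer array sets and the number of members that rose and fell at the right of each panel. The G2 and M phase list lies at 1.49 between reporter classes of pre-CD8 and at -1.11 between stages of Id2-GFP- cells.

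The reporter differences of the 2 stages, which share no array, were set against each other over 19938 genes. Across genes, which are not independent replicates, they correlated with a Pearson r of 0.63 and a Spearman rho of 0.49. Within the brighter and dimmer sets r was 0.61 and 0.51, and between sets 0.53 and 0.56, and over differences of single arrays r ranged from 0.04 to 0.74. Of the 119 genes that rose in CDP 99 also rose in pre-CD8, where independent lists would share 4.24 (Fisher's exact test, p = 6.06e-125), and 118 had the same sign. Among them were H2-Aa, Cd74, Camp, S100a8, Cd226 and Ifi205. Both lists came from a single fit that gives each gene the same standard error in both comparisons. Genes also move together. The Fisher test assumes neither, so its p-value and the 4.24 can overstate the agreement.

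**Figure D3:**
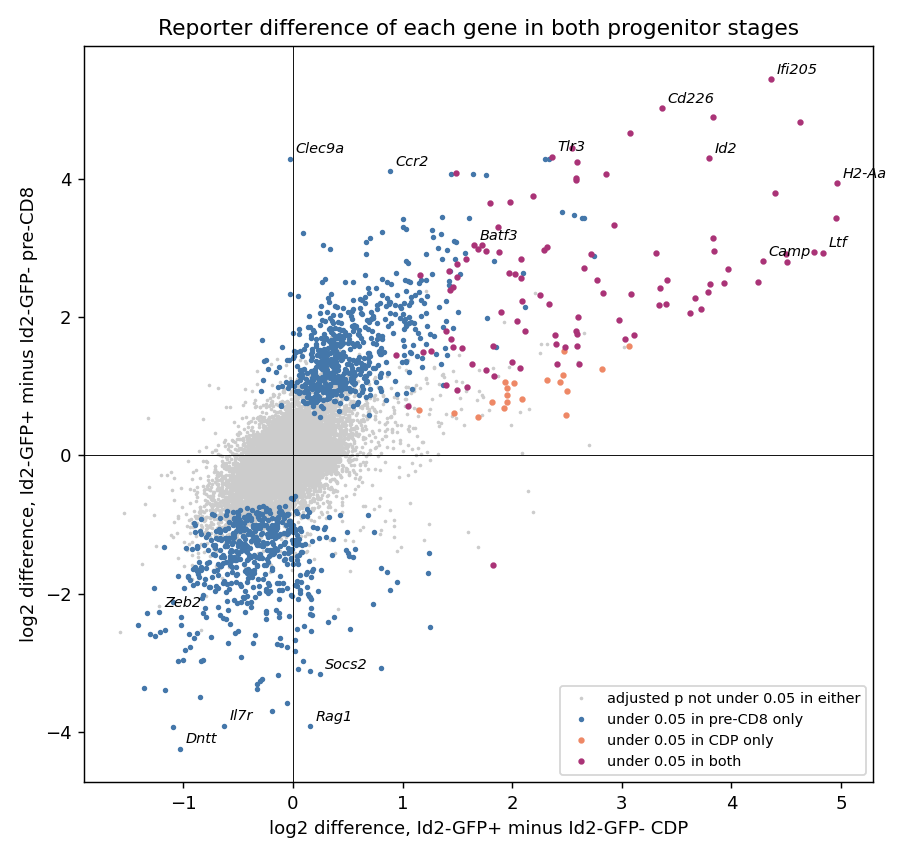
Log2 difference between Id2-GFP+ and Id2-GFP- cells of each gene in CDP (horizontal axis) and in pre-CD8 (vertical axis), with colours for genes at an adjusted p under 0.05 in either or both stages. Clec9a lies at -0.02 in CDP and 4.29 in pre-CD8.

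Whether a reporter difference itself differed between stages was tested by the interaction contrast. Clec9a differed by 4.29 ± 0.40 in pre-CD8 and by -0.02 ± 0.40 in CDP, an interaction of 4.31 ± 0.56 (adjusted p of 0.0397). Ccr2 had a larger reporter difference in pre-CD8, by 3.22 ± 0.28. In the other direction were Socs2, a suppressor of cytokine signalling, at -3.41 ± 0.23, Lax1 and Lat, adaptors of lymphocyte receptors, at -3.27 ± 0.34 and -3.03 ± 0.30, Rag2 at -3.13 ± 0.20, Arpp21 at -2.95, Slc18a1 at -2.95, Bank1 at -2.84, Ifi206 at -2.69 and Sema3d at -2.46. By limma 7 genes had a positive and 22 a negative interaction, a positive share of 24.1% that was 36.7% after median centring (11 and 19) and 46.2% after quantile normalization (73 and 85). The array set as a block gave 815 and 677. Without Id2-GFP+ CDP replicate 1 the count was 15, without Id2-GFP+ CDP replicate 2 it was 3, without Id2-GFP- pre-CD8 replicate 1 it was 5, and without any other single array (either Id2-GFP- CDP array, Id2-GFP- pre-CD8 replicate 2, either Id2-GFP+ pre-CD8 array) it was 2. Rag2 and Socs2 kept their calls without each array in turn, and the other 9 named lost them without at least 6 of the 8, with adjusted p-values of at most 0.189. Batf3, Irf8, Zeb2 and Id2 did not pass, at 1.39, 1.06, -1.04 and 0.51.

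Stages were compared next, first among Id2-GFP- cells. In Id2-GFP- pre-CD8 over Id2-GFP- CDP the lymphocyte adaptor gene Lax1 rose by 4.64 ± 0.24, Rag1 by 4.08 ± 0.32, Dntt by 3.86 ± 0.47, Il7r by 3.64 ± 0.26 and the B lineage transcription factor gene Ebf1 by 3.18 ± 0.33. Myl10, the purinergic receptor gene P2ry14, the guanylate-binding protein gene Gbp4, Socs2, Ctla2a and Rtp4 rose by 4.37, 4.15, 3.69, 3.59, 3.57 and 3.55. F13a1 (coagulation factor XIII) fell by 3.63 ± 0.47, Clec9a by 3.41 ± 0.40, the dectin gene Clec7a by 2.82 ± 0.27 and Ccr2 by 2.58 ± 0.20. Met, Upk1b, Abca9, Igsf6, Mefv and Fkbp1b fell by 2.93, 2.83, 2.82, 2.76, 2.62 and 2.48. Csf1r fell by 1.94 ± 0.23. Id2, Batf3, Zbtb46, Irf8 and Zeb2 did not pass, at 0.82, 0.09, 0.00, -0.81 and -0.91. By limma 206 genes rose and 118 fell, a rising share of 63.6% that was 53.2% after median centring (183 and 161) and 48% after quantile normalization (401 and 435), and the array set as a block gave 1161 and 1325. The total of 324 was 104 without Id2-GFP- CDP replicate 1, 77 without Id2-GFP- CDP replicate 2, 143 without Id2-GFP- pre-CD8 replicate 1 and 142 without Id2-GFP- pre-CD8 replicate 2. Without 1 or more of these 4 arrays Dntt, Rtp4, F13a1, Clec9a, Csf1r, Met, Upk1b, Abca9, Igsf6 and Mefv lost their calls, with adjusted p-values of at most 0.115.

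4 of 16 B lineage markers rose in Id2-GFP- pre-CD8 over Id2-GFP- CDP (6 adjusted over the list alone), Rag2 at 2.74, Bank1 at 2.35, Rag1 and Ebf1, with a median of 0.39 (camera adjusted p of 2.29e-09, and adjusted p = 0.123 with an estimated correlation). Beside them 4 of 20 pDC markers rose (8 rose and 5 fell adjusted over the list alone), the gut-homing receptor Ccr9 at 3.51 ± 0.31, Blnk at 2.79, Tlr7 at 2.60 and Dntt (adjusted p = 0.497 with an estimated correlation), and 1 of 19 T, NK and ILC markers, Il7r (3 adjusted over the list alone, adjusted p = 0.391 with an estimated correlation). 5 of 21 interferon response genes rose (10 rose and 1 fell adjusted over the list alone), with the RNA sensor Ddx58 at 3.45 and Oas2 at 2.58 (adjusted p = 0.497 with an estimated correlation). 4 of 9 MHC class II genes rose (5 adjusted over the list alone), with Cd74 at 2.75, H2-Ob at 2.67 and H2-Aa at 2.65 (adjusted p = 0.391 with an estimated correlation). 2 of 24 early progenitor genes rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.497 with an estimated correlation), Mycn at 3.24. The set as a block gave 7 rising B lineage markers, 9 rising and 5 falling pDC markers, 5 rising T, NK and ILC markers, 14 and 2 interferon response genes, 5 and 1 MHC class II genes and 13 and 2 early progenitor genes.

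Falling in that comparison were 9 of 34 G2 and M phase genes (34 adjusted over the list alone), with Hmmr at -1.43, Nuf2 at -1.41, Birc5 at -1.35 and a median of -1.11, and of -1.02 and -1.24 within the sets. Camera's adjusted p was 2.07e-39, against adjusted p = 0.321 with an estimated correlation. No S phase gene passed by limma over all genes (4 of 29 fell adjusted over the list alone and 22 with the set as a block), with a median of -0.59 (adjusted p = 0.497 with an estimated correlation). 5 of 16 monocyte and macrophage markers fell (9 adjusted over the list alone), the fractalkine receptor Cx3cr1 by 1.97 and Ms4a6c by 1.91 (camera adjusted p of 8.4e-11, and adjusted p = 0.229 with an estimated correlation). 1 of 15 neutrophil and granule genes, Prtn3, fell by 2.20 (6 rose and 3 fell adjusted over the list alone), and the list's median of 0.10 and mean of -0.13 differed in sign (camera adjusted p of 0.587). 1 of 22 cDC1 markers rose and 1, Clec9a, fell, with a median of -0.05 (camera adjusted p of 0.587). With the set as a block 34 G2 and M phase genes fell, 9 monocyte markers fell and 1 rose, 6 neutrophil and granule genes rose and 6 fell, and 4 cDC1 markers rose and 4 fell. Hmmr, Nuf2, Birc5, Blnk, Tlr7, Ddx58, Oas2, Prtn3 and Clec9a lost their calls without 1 or more arrays, with adjusted p-values of at most 0.228.

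**Figure D4:**
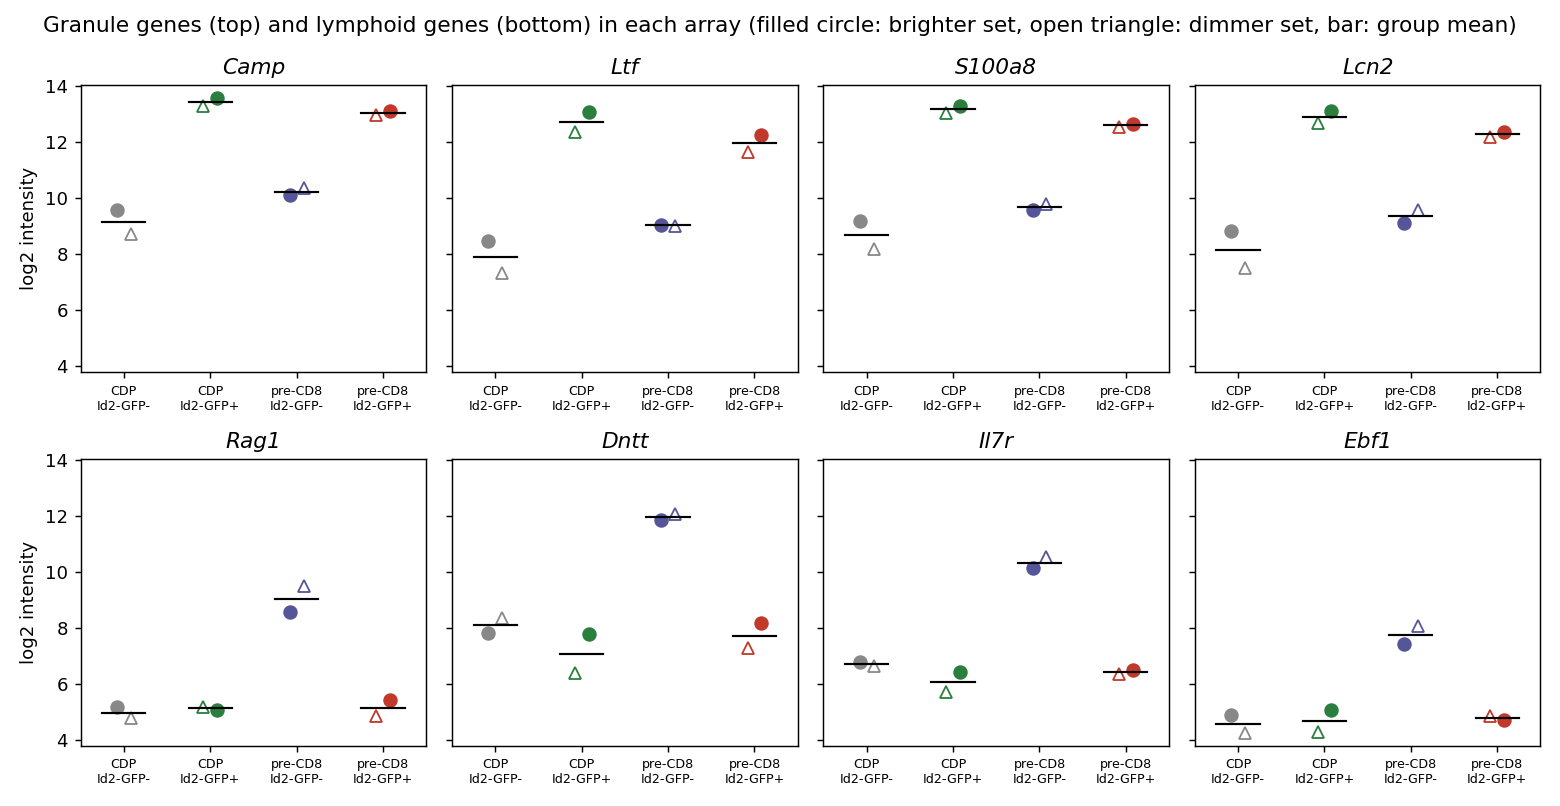
Log2 intensity (vertical axis) of 4 granule genes (top) and 4 lymphoid genes (bottom) on each array by population (horizontal axis), with filled circles for the brighter array set, open triangles for the dimmer set and bars for group means of 2 arrays. Camp lies at 13.44 and 13.04 in Id2-GFP+ CDP and pre-CD8 against 9.15 and 10.23 in the Id2-GFP- groups, and Dntt lies highest in Id2-GFP- pre-CD8.

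Among Id2-GFP+ cells, no gene passed between pre-CD8 and CDP. The 5 genes with the smallest p were Gcsam at 2.49 ± 0.28, the lectin gene Clec4b1 at 2.04 ± 0.21, H2-Ab1 at 1.92 ± 0.22, Csf1r at -2.33 ± 0.23 and the fibronectin gene Fn1 at -3.09 ± 0.33, each with an adjusted p of 0.0577. Batf3 differed by 1.48 ± 0.23, Zeb2 by -1.95 ± 0.41, Id2 by 1.33 ± 0.48 and Clec9a by 0.90 ± 0.40. By limma 0 genes rose or fell and 643 had an unadjusted p under 0.05, fewer than 5% of the genes tested. The array set as a block gave 194 rising and 220 falling genes, quantile normalization 15 and 8, the filter on dim genes 6 and 3, and leaving out Id2-GFP+ CDP replicate 1 gave 1. Adjusted over the list alone, 10 of 22 cDC1 markers and 7 of 9 MHC class II genes were higher in pre-CD8, with medians of 0.75 and 1.62, and 9 and 7 passed over all genes with the set as a block. 7 of 16 monocyte markers were lower and 1 higher adjusted over the list alone, and 3 of 15 neutrophil and granule genes were lower, with medians of -0.64 and -0.83. With the set as a block 8 monocyte markers fell and 1 rose, and 5 neutrophil and granule genes fell. Camera's adjusted p was 1.32e-29 for cDC1 and for MHC class II, 7.93e-12 for monocyte and 9.28e-16 for neutrophil genes, against adjusted p = 0.0938, 0.0938, 0.0966 and 0.182 with an estimated correlation.

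The stage differences of the 2 reporter classes, which also share no array, correlated across genes with a Pearson r of 0.16 and a Spearman rho of 0.06. Within the brighter and dimmer sets r was 0.12 and 0.14, and between sets 0.20 and 0.07, and over differences of single arrays r ranged from -0.35 to 0.52. Without Id2-GFP+ pre-CD8 replicate 1 r was 0.0861. Of the 324 genes past the threshold among Id2-GFP- cells, 212 had the same sign among Id2-GFP+ cells.

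Id2-GFP+ pre-CD8 and Id2-GFP- CDP, the corners of the square of stage and reporter, were compared with 277 genes rising and 80 falling by limma. H2-Aa and Cd74 rose most, by 6.58 ± 0.28 and 6.55 ± 0.32, and H2-Eb1 and H2-Ab1 by 5.27 and 4.85, with Plbd1 at 5.68, Ifi205 at 5.23, Id2 at 5.12 ± 0.48, Slamf7 at 4.97, Tlr3 at 4.89 and Cd226 at 4.67. Falling genes included F13a1 by 4.13 ± 0.47, the granule protease gene Ctsg by 3.66, Cd69 by 3.22, Zeb2 by 3.17 ± 0.41, Csf1r by 3.03 ± 0.23, the myeloperoxidase gene Mpo by 2.71 and Cd93 by 2.64. Batf3 rose by 3.13 ± 0.23 and Zbtb46 by 2.05, and Irf8 and Clec9a did not pass at 0.33 and 0.88. Of 22 cDC1 markers 11 rose (14 adjusted over the list alone), and 7 of 9 MHC class II genes rose (9 adjusted over the list alone), both with a camera adjusted p of 6.52e-28 and adjusted p = 0.0671 with an estimated correlation. Beside them 8 of 15 neutrophil and granule genes rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 0.296 with an estimated correlation). The rising share of 77.6% was 64.1% after quantile normalization (581 and 326), and the set as a block gave 1390 and 1764 (16 rising cDC1 markers, 9 rising MHC class II genes, 10 rising and 3 falling neutrophil and granule genes). Without Id2-GFP- CDP replicate 1 or 2 the total of 357 was 77 or 144, without Id2-GFP+ pre-CD8 replicate 1 or 2 it was 215 or 83. F13a1, Ctsg, Cd69, Zeb2, Mpo and Zbtb46 lost their calls without 1 or more of these arrays, with adjusted p-values of at most 0.283.

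The remaining pair, Id2-GFP- pre-CD8 over Id2-GFP+ CDP, differed in 415 rising and 560 falling genes. Dntt rose by 4.89 ± 0.47, Lax1 by 4.48 ± 0.24, Myl10 by 4.42, Il7r by 4.27, P2ry14 by 4.05, Rag1 by 3.92, Blnk by 3.88, Ctla2a by 3.62, Cmah by 3.56 and Gimap6, a GTPase of lymphocytes, by 3.52. Ifi205 fell by 4.58 ± 0.37, Serpinb10 by 4.43 ± 0.42, Ly6a2 by 4.39, Ifitm6 by 4.32, the collagenase gene Mmp8 by 4.28, Fn1 by 4.15, Chil3 by 4.13, Clec4a2 by 3.98, Trem3 by 3.95 and Cd209a by 3.90, with Clec9a at -3.39. Id2 fell by 2.97 ± 0.48. 12 of 15 neutrophil and granule genes fell (13 adjusted over the list alone), as did 28 of 34 G2 and M phase genes (34 adjusted over the list alone), 9 of 16 monocyte markers (13 adjusted over the list alone) and 7 of 22 cDC1 markers (9 adjusted over the list alone), each with adjusted p = 0.189 with an estimated correlation. 6 of 20 pDC markers rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 0.42 with an estimated correlation), and 6 of 24 early progenitor genes rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 0.326 with an estimated correlation). The set as a block gave 2406 and 1970 genes. Among lists it had 14 neutrophil and granule genes, 34 G2 and M phase genes and 13 monocyte markers falling, 1 cDC1 marker rising and 10 falling, 10 and 3 pDC markers and 18 and 2 early progenitor genes. Without Id2-GFP+ CDP replicate 1 or 2 the total of 975 was 597 or 631, and without Id2-GFP- pre-CD8 replicate 1 or 2 it was 502 or 436, while Id2 lost its call without Id2-GFP+ CDP replicate 1, with an adjusted p of 0.0672.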

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

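The interaction test, the gene lists and the named genes were fixed before the values were seen, and every test that weighs an explanation in this part was chosen after the result it weighs had been seen.

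A test of the difference itself set apart 29 genes whose reporter difference differed between stages. Given as the pre-CD8 difference minus the CDP difference, the 10 with the smallest p were Rag2 at -3.13, Socs2 at -3.41, Sema3d at -2.46, Ccr2 at 3.22, Ifi206 at -2.69, Bank1 at -2.84, Slc18a1 at -2.95, Lat at -3.03, Lax1 at -3.27 and Arpp21 at -2.95. The same test by camera set apart 16 lists. Their interaction medians were 0.88 for cDC1 markers (adjusted p = 0.202 with an estimated correlation), -0.51 for pDC markers (0.453), -1.14 for early progenitor genes (0.396), 0.0266 for monocyte and macrophage markers (0.456), -1.24 for neutrophil and granule genes (0.448), -0.38 for B lineage markers (0.202), -0.32 for T, NK and ILC markers (0.369) and -0.23 for basophil, mast cell and eosinophil markers (0.453). Further medians were 0.46 for S phase (adjusted p = 0.466 with an estimated correlation), 1.12 for G2 and M phase (0.312), -1.07 for interferon response (0.448), 0.45 for cholesterol synthesis (0.312), 0.16 for oxidative phosphorylation (0.608), 0.0695 for chemokine receptors and migration (0.369), 0.57 for toll-like receptors and adaptors (0.453) and -0.22 for helix-loop-helix genes (0.456). By limma over all genes 1 cDC1, 2 monocyte and 1 chemokine member had a positive interaction, 3 B lineage members and 1 T, NK and ILC member a negative one, and no member of the other 11 lists passed. With the set as a block the positive and negative interactions in the first 8 lists, in the same order, numbered 10 and 0, 3 and 5, 0 and 13, 5 and 2, 0 and 8, 2 and 6, 0 and 2, and 1 and 2. In the further 8 they numbered 6 and 0, 33 and 0, 1 and 11, 4 and 0, 2 and 0, 4 and 3, 6 and 1, and 0 and 1, and 13 of the 16 lists kept camera's call.

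Probe sets without a single gene name stand outside the comparisons of genes. Of 7064 such probe sets 200 passed between the reporter classes of pre-CD8, 106 higher and 94 lower in Id2-GFP+ cells.

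Of 15 neutrophil and granule genes 9 rose and 0 fell with the reporter in CDP (11 and 2 with the set as a block), and 10 rose and 1, Mpo, fell in pre-CD8 (12 and 2), and neutrophil-lineage cells or their RNA in the Id2-GFP+ sorts would raise other neutrophil genes as well. A second list of 19 measured neutrophil genes, 2 of them also in a fixed list, had a median of 2.59 in CDP (12 rose, 0 fell, and 16 and 0 with the set as a block) and 1.32 in pre-CD8 (10 rose, 0 fell, and 14 and 2), which fits that explanation without excluding others. All 19 lay lower in Id2-GFP+ pre-CD8 than in Id2-GFP+ CDP, with a median of -1.03, where 0 passed in the main fit and 11 fell with the set as a block. Each set holds 1 array of every group, so an additive difference between the sets cancels from these comparisons by design and was not tested by them. The lowest within-set median of the fixed list was 2.21, so the rise was not confined to 1 set. Expression of these genes by the Id2-GFP+ progenitors themselves was not tested and stays open.

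Between Id2-GFP- pre-CD8 and Id2-GFP- CDP 4 of 16 B lineage markers, 4 of 20 pDC markers and 1 of 19 T, NK and ILC markers rose (7, 9 and 5 with the set as a block), among them Rag1, Dntt and Il7r. Committed B cells in the sort stay open: 13 B commitment genes had a median of 0.31 with 12 positive and 1 passing, but that list leaves out Rag1, Rag2, Ebf1 and Bank1 and has 1 member at log2 8 or above in Id2-GFP- CDP. Plasmacytoid dendritic cells stay open, with a median of 0.11 and an SD of members of 0.92 over 16 abundant pDC genes that leave out the 4 pDC markers that rose. An additive difference between the array sets cancels from this comparison by design, as each set holds 1 array of every group. Members of the 3 lists above 1 in 1 set had a median of at least 2.54 in the other. These rises were therefore not confined to 1 set. This was the last of 3 forms of the test run. The earlier forms were the whole B lineage list (lower within-set median 0.27) and the 9 members that rose (at least 2.18 in each set). Expression by the Id2-GFP- progenitors themselves was not tested and stays open.

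The arrays split into a brighter and a dimmer set with 1 array of each group in each, and with the group in the model 7284 genes were higher and 2495 lower in the brighter set. The sets were drawn by the mean intensity of these same arrays, so the counts do not test whether the sets differ. Scaling that quantile normalization removes is excluded as the whole cause of the split. After it the smallest absolute correlation of within-group array differences was 0.584. The labels used here do not say that the 8 arrays were processed together, and separate processing of the sets was not tested. Of the 26 lists 8 passed between the sets, each higher in the brighter set: ribosome biogenesis (median 0.61), interferon response (0.56), early progenitor (0.51), neutrophil and granule genes (0.59), S phase (0.35), G2 and M phase (0.33), MHC class I (0.26) and oxidative phosphorylation (0.20), and none passed when the correlation was estimated (each adjusted p = 0.972 with an estimated correlation). Cell stress or handling stays open, as the immediate early and stress list had a median of 0.47 with a camera adjusted p of 0.182. Its members went both ways. Hspa1a, Jun and Dusp1 were higher by 3.23, 3.09 and 2.11. Leaving aside the symbol classes not named by size, these were the largest differences between the sets among all genes tested. Fosb, Fos, Zfp36, Ier2, Ppp1r15a, Btg2, Egr1 and Nr4a1 also passed upward, at 0.37 to 1.67. Only Jund, Egr2 and Atf3 passed downward, at -0.57, -0.40 and -0.28. No other biological explanation was tested, and the labels used here give no date, slide or batch.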

How the results depend on the processing

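The intensity set block, alone and after quantile normalization, was chosen after the results were seen, and all other settings were fixed before. Genes differing are given in the order reporter in CDP (119), reporter in pre-CD8 (1249), stage in Id2-GFP- (324), stage in Id2-GFP+ (0), Id2-GFP+ pre-CD8 over Id2-GFP- CDP (357), Id2-GFP- pre-CD8 over Id2-GFP+ CDP (975) and interaction (29). The set block gave 1566, 4822, 2486, 414, 3154, 4376 and 1492, and after quantile normalization 1480, 4952, 2540, 421, 3186, 4605 and 1419. Quantile normalization alone gave 196, 2475, 836, 23, 907, 2021 and 158. The upper 60% of genes by mean gave 9 for stage in Id2-GFP+ and 49 for the interaction. Replicate numbers were shared between groups without a stated meaning, and array deviations of equal number correlated between groups from -0.69 to 0.71. The replicate block gave 157 for stage in Id2-GFP-, 208 and 642 for the next pairs and 6 for the interaction, and moved no other count by over 1.5 times. Crossing the numbers between reporter classes is the same fit as the set block, with the counts given for it. Leaving out each array in turn gave 35 to 126, 466 to 1313, 77 to 326, 0 to 1, 77 to 370, 436 to 867 and 2 to 15, where a lone array was assumed to vary like the other groups. Those fits have fewer arrays, and for the other settings the cause was not tested. The reporter overlap r ranged from 0.515 to 0.646 and the stage overlap r from 0.0861 to 0.190 across left-out arrays. All 113 list calls were lost with an estimated correlation, 78 by fry, 12 with the filter, 7 with the set block and 0 with the replicate block. With an estimated correlation the smallest camera adjusted p of 182 was 0.0671, so that setting had little power and did not separate the lists. A higher correlation was not the whole reason for the loss of all calls with an estimated correlation. That setting also tests on the 4 residual degrees of freedom of the fit. For the reporter in CDP the chemokine and migration list had an estimate of 0.0154 against the preset 0.01. Its camera adjusted p still went from 2.00e-05 to 0.113. Among named genes 61 calls were lost with the replicate block and 26 when fitting only the arrays compared. Medians of 2 lists turned sign without Id2-GFP+ CDP replicate 2: the interferon response list for the reporter in CDP, at -0.0024 (range to 0.4528), and the early progenitor list for stage in Id2-GFP+, at 0.1843 (range from -0.5498) and 0.14 without Id2-GFP+ pre-CD8 replicate 1, and the cause was not tested. Named genes kept their sign without each array in turn, and 14 of 28, 59 of 84, 22 of 51, 22 of 51, 55 of 80 and 2 of 11 passing ones kept their call (reporter in CDP, reporter in pre-CD8, stage in Id2-GFP-, then the last 3 comparisons). Every setting fixed before was run. No measure of signal over background was used here, so differences between dim genes near background are limited in a way these values cannot size.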

Other observations

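Gene families, formed by symbol stem and tested after the data had been seen, held further groups, and near-identical paralogs on the array can share probes. Of 8 measured Gimap genes, GTPases of lymphocyte survival, 7 rose in Id2-GFP- pre-CD8 against Id2-GFP- CDP, with a family median of 2.42, Gimap6 at 3.38 ± 0.24 (log2 ± SE, n = 2 a group), Gimap5 at 2.97 ± 0.31 and Gimap7 at 2.88 ± 0.39 (camera adjusted p of 2.02e-18 over 590 families, and adjusted p = 0.7 with an estimated correlation). Between the reporter classes of pre-CD8 6 of the 8 fell, with a median of -2.19 and Gimap6 at -3.18 (camera adjusted p of 2.54e-07, and adjusted p = 0.999 with an estimated correlation). Both Gimap comparisons use the same Id2-GFP- pre-CD8 arrays, so they are not independent. Guanylate-binding protein (Gbp) genes, induced by interferon, had 6 of 8 falling between those classes, with Gbp7 at -3.49 and Gbp5 at -2.45 (camera adjusted p of 3.16e-05, and adjusted p = 0.999 with an estimated correlation).

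Of 10 Hoxa genes, homeobox factors of progenitors, 4 fell in Id2-GFP+ pre-CD8 against Id2-GFP- pre-CD8, Hoxa9 at -2.36 ± 0.31, Hoxa5 at -1.72 ± 0.23, Hoxa6 at -1.57 ± 0.28 and Hoxa3 at -0.92 ± 0.19 (camera adjusted p of 7.12e-04, and adjusted p = 0.999 with an estimated correlation). Of 9 measured genes of the Ifi200 family, not tested as a group, 4 rose in the same comparison, 2 fell and 3 did not pass. Ifi205, Ifi207, Ifi209 and Ifi203 rose by 5.44 ± 0.37, 4.07 ± 0.35, 1.83 ± 0.22 and 0.81 ± 0.19, and Ifi206 and Ifi213 fell by 2.67 ± 0.18 and 1.69 ± 0.27.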
